A study of Mus musculus with 8 samples.

How the data were processed

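Brain RNA of 8 adult male C57Bl6J mice aged 5 to 6 months was measured on 4 spotted cDNA arrays. Per the labels, 4 mice were untreated controls and 4 had their hindlimbs unloaded by tail suspension, a ground model of weightlessness in which the rear of the body is lifted off the cage floor. RNA of 1 whole brain, 60 µg in each case, was labelled with Cy5 or Cy3. Each array then received the labelled cDNA of 2 animals of the same group at 50 °C. The arrays thus held control replicates 1 and 2, control replicates 3 and 4, unloaded replicates 1 and 2, and unloaded replicates 3 and 4. The odd replicate of each pair carried Cy5 and the even one Cy3. No array held both groups, so the group comparison lay between arrays, while the dyes were balanced within each group.

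The deposited scanner values were spot intensities in linear units, neither normalized nor background-subtracted, measured with GenePix Pro 3.0.6.90 per the file headers. For every spot and dye they gave the mean and median of the foreground pixels and the median and SD of the local background. The deposited files also gave the percent of saturated pixels per spot, and a flag from the image software. A further deposited table held log2 values made by the authors, with each of its 8 columns at a median of 0. Comparison with the scanner values showed that this table left out flagged spots and that every listed spot had a foreground median of at least 2 times its background median in both dyes. Its columns correlated with log2 background-subtracted intensity of the same array and dye at r from 0.955 to 0.994 across spots. The steps that the authors used to make it, and its scaling between arrays, were not given in the sources used here.

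The array held 28704 spots in 48 print blocks. The name and identifier columns of the scanner files were empty, with 0 spots named, and the reference tables in use did not pair spots with genes. Spots are therefore given by their number in the files and by print block, column and row, and no gene is named. The 31 gene lists fixed in advance, which covered synapses, ion channels, cell types, brain regions, stress responses and metabolism, were not tested for the same reason. The choice of 1 spot per gene was not made either.

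Foreground means were corrected with the normexp method of limma 3.58.1 (offset 50) in R 4.3.3. Log ratios were normalized within each array by loess, with flagged spots at weight 0, and mean intensities were equalized between arrays by quantiles (Aquantile). The 8 log2 intensities were then taken apart by dye, and flagged spots were left out. A spot was well above background where its foreground median exceeded the background median by over 2 background SD. Spots entered the tests when they were well above background in at least 4 of the 8 samples and not flagged on at least 3 of the 4 arrays, which left 22844 spots. Saturated spots were kept.

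Unloaded and control brains were compared by lmFit and eBayes of limma, with terms for group and dye and with the array as a random block. The correlation within arrays came from duplicateCorrelation, which uses statmod 1.5.0. The p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The spread between animals was taken as the median absolute log2 ratio between the animals of an array, without a test. Fixed in advance, the rule for single items took the spots with the largest change past the adjusted threshold and no overlap between the groups, filled up with non-overlapping spots of the smallest unadjusted p. As no spot has a gene name, only 2 spots per direction are given.

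The fit was tested on simulated values in which 200 of 22844 spots were changed. Spread per spot and the correlation within arrays were set as the fits of the real data estimated them. All samples of a spot were given the same spread, so the wider spread on the array of control replicates 1 and 2 was not reproduced. Of 100 spots changed 2-fold, 19 were recovered with the settings of all 8 samples, and of 100 changed 4-fold, 81 were recovered, next to 12 false calls. With the settings of the 7 samples without control replicate 2, the recovered numbers were 5 of 100 and 85 of 100, next to 6 false calls. The correlation within arrays was set to 0.18 and estimated as 0.11 in the first simulation, and set to 0.66 and estimated as 0.65 in the second.

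The alternatives chosen before the data were examined covered the block for the array, the dye term, a replicate block, background correction, normalization within and between arrays, the foreground measure, the filter on dim spots, the authors' table, and leaving out each replicate or array. Centring on print blocks, and combinations with control replicate 2 or its array left out, were added after the data were seen.

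Both control arrays were scanned on 1 day and both unloaded arrays on another, per the file headers, so scan day and group cannot be told apart. The Cy5 detector was set to 660 V for the array of control replicates 1 and 2 and to 760 V for the other 3 arrays, with 670 V for Cy3 on all 4. The number of arrays, 2 per group, limits the precision of every comparison.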

Results

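Whole-brain expression was measured in 4 control mice and 4 tail-suspended, hindlimb-unloaded mice, with 2 mice of 1 group on each of 4 spotted cDNA arrays. Between 3483 and 6421 of the 28704 spots were flagged per array, most on the array of control replicates 1 and 2. The number of spots well above background ranged from 17152 in control replicate 2 to 24891 in unloaded replicate 3. On the mean of its 2 samples, it was 20265 and 21186 on the control arrays and 22356 and 23866 on the unloaded arrays. Median foreground intensity in Cy5 was 466 and 577 on the control arrays and 742 and 835 on the unloaded arrays, and in Cy3 it was 296 and 534 against 442 and 760. Median background intensity differed mainly by dye, with 47 to 79 in Cy5 and 145 to 178 in Cy3. Both animals of an array share its conditions, and the smallest p of an exact two-sided permutation test of 2 arrays against 2 is 0.333, so that test could not pass 0.05 in any of these measures.

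The first question was how far animals of 1 group differed, which the design measured within each array. The animals of an array differed by a median of 0.18 on the log2 scale for control replicates 3 and 4, and by 0.17 for each of the pairs of unloaded animals. These values correspond to 1.13-fold in each case. Control replicates 1 and 2 differed by a median of 0.59, or 1.51-fold. On that array 24.8% of the tested spots differed over 2-fold between the animals, against 0.765% to 3.20% on the other 3 arrays. These ratios hold the difference between animals together with dye and measurement error, and with 2 arrays per group the difference in spread between control and unloaded animals was given without a test.

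**Figure D1:**
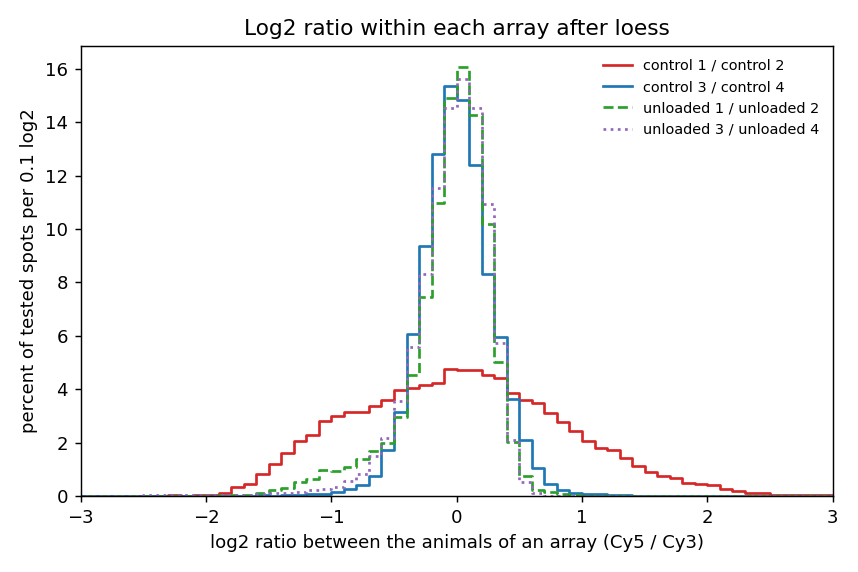
Percent of tested spots (y axis, per 0.1 of log2 ratio) against the normalized log2 ratio of Cy5 over Cy3 between the animals of each array (x axis), 1 line per array. The line of control replicates 1 and 2 is wide, with a median size of 0.59, while the other 3 lines, with 0.17 to 0.18, lie close together.

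Across the 21392 tested spots that no array had flagged, normalized log2 intensities of animals on the same array correlated at r from 0.966 to 0.975 in the 3 pairs without control replicate 2. Animals of the same group on different arrays had a mean r of 0.933 ± 0.023 (SD, 6 pairs), and animals of different groups 0.931 ± 0.015 (SD, 12 pairs). The difference between these means was smaller than the spread between pairs. Of the pairs of the same group on different arrays, those of controls had r of 0.949 and 0.958, and those of unloaded animals 0.904 to 0.942. Each of the 4 unloaded samples had a lower mean r with the unloaded samples of the other array than with control replicates 1, 3 and 4. These means were 0.905 against 0.923, 0.940 against 0.946, 0.924 against 0.927 and 0.921 against 0.926 for unloaded replicates 1 to 4. After print blocks were centred, the order of these means held for unloaded replicates 1 and 2 and was reversed for unloaded replicates 3 and 4. The order thus depended on the processing. Control replicate 2 stood apart from all others, at r = 0.818 with its array partner, 0.819 and 0.843 with the other controls, and 0.731 to 0.784 with the unloaded animals. These correlations are across spots, which are not independent replicates.

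**Figure D2:**
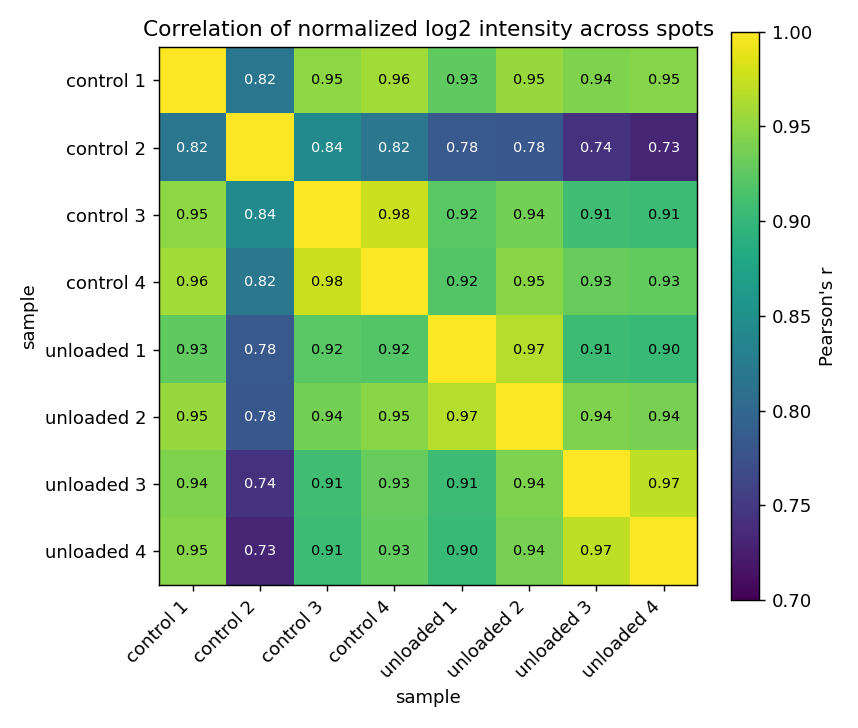
Pearson's r of normalized log2 intensity across spots (colour and printed value) for every pair of the 8 samples, with samples on both axes. Control replicate 2 has the lowest values in every row, from 0.73 to 0.84, and the 3 other array pairs the highest, with 0.97 to 0.98.

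The second and main question was which transcripts differed between unloaded and control brains. None of the 22844 spots passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 0.262. From foreground medians in place of means 1 spot passed, and without the second unloaded array 2 spots passed. With the first control array left out and print blocks centred, a setting added after the data were seen, 8 passed. At an unadjusted p under 0.05 there were 2762 spots, 12.1% of those tested, where 5% would be 1142. Of these, 1075 were higher and 1687 lower in unloaded brains. The balance of higher and lower spots varied with the processing. With only median scaling between arrays it was 751 higher and 2083 lower. In the authors' deposited log2 values, which differ in several steps at once, it was 525 higher and 149 lower. The median log2 difference over the 17841 spots tested in those values was 0.20. Each of their columns has a median of 0 over its own listed spots, from 14648 to 21196 per array. In the main fit the median log2 difference between the groups was 0.02, with 5% of spots below -0.76 and 5% above 0.63. A difference of at least 2-fold was measured at 129 spots with higher and 425 with lower values in unloaded brains. The 95% confidence interval of a spot of median standard error, 0.26, reached 0.59 on the log2 scale to either side before any adjustment for the number of spots.

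The count of spots at an unadjusted p under 0.05 moved by over 1.5 times when some single samples were left out. Without control replicate 2 it was 1300, or 5.69% of the spots, with 0 past the adjusted threshold and a lowest adjusted p of 0.259. It was 1825 without control replicate 1, 4838 without control replicate 4 and 4248 without unloaded replicate 1. Without any other single sample it was 2015 to 2798. The estimated correlation between animals of an array was 0.18 with all 8 samples, 0.66 without control replicate 2 and 0.83 without control replicate 1. This estimate was -0.04 without control replicate 4 and -0.03 without unloaded replicate 1, the fits with the highest counts.

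**Figure D3:**
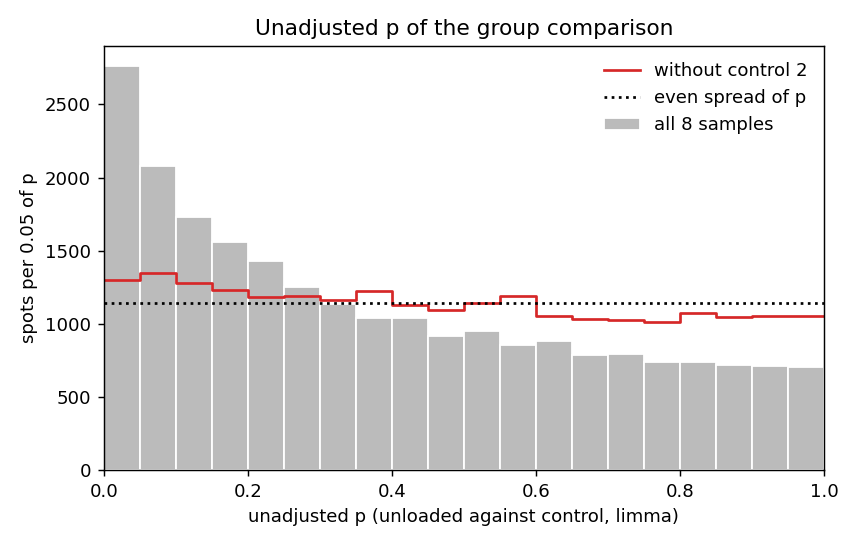
Number of tested spots (y axis) per 0.05 of unadjusted p (x axis) for unloaded against control brains, with all 8 samples (bars) and without control replicate 2 (line), and the height that evenly spread p-values would give (dotted). The lowest bar interval holds 2762 spots with all samples and 1300 without control replicate 2.

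Spots at an unadjusted p under 0.05 made up a larger share of the bright than of the dim spots. In the dimmest 25% of the tested spots the share was 6.46%, with 127 spots higher and 242 lower in unloaded brains, and in the brightest 25% it was 19.8%, with 370 higher and 759 lower. Without control replicate 2 the counts were 83 and 101 among the dimmest and 144 and 369 among the brightest. In the 21392 spots measured on every array, the 4 unloaded and the 4 control values did not overlap at 3036 spots, 14.2% against the 2.86% that chance gives for independent samples. Unloaded values were higher at 1528 of these spots and lower at 1508. Without control replicate 2 the groups did not overlap at 3912 of the 21392 spots, 18.3% against the 5.71% that chance gives for independent samples. Animals of an array were not independent, so neither share is a test. With all 8 samples, the other 2 splits that keep arrays whole gave 1138 and 1325 non-overlapping spots.

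The spots with the smallest unadjusted p among those without overlap are given as examples, none of which passed the adjusted threshold. Spot 1918 (print block 4, column 20, row 5) had a log2 intensity of 11.60 ± 0.27 in control and 9.87 ± 0.27 in unloaded brains (SD, n = 4 each). Its log2 difference was -1.73 with a standard error of 0.24, and its adjusted p from limma was 0.304. Spot 21552 (block 37, column 24, row 1) had 12.06 ± 0.11 in control and 10.83 ± 0.14 in unloaded brains (SD, n = 4 each), a difference of -1.23 with a standard error of 0.19 (limma, adjusted p = 0.367). Spot 7688 (block 13, column 18, row 20) had 10.79 ± 0.39 in control and 11.97 ± 0.14 in unloaded brains (SD, n = 4 each). The difference was 1.18 with a standard error of 0.22, and the adjusted p from limma was 0.369. Spot 2638 (block 5, column 12, row 10) had 9.41 ± 0.22 and 10.46 ± 0.13 (SD, n = 4 each), a difference of 1.05 with a standard error of 0.20 and an adjusted p from limma of 0.369. After print blocks were centred, the difference was 0.76 at spot 7688 without control replicate 2 and 0.63 at spot 2638 without the first control array. Intensities of different spots cannot be set against each other.

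A further question, whether groups of genes such as synaptic, glial or stress-response genes moved together, was not answered here, because the spots carried no gene names. Both arrays of a group were scanned on the same day and no day held both groups, so a difference between the groups cannot be told apart from one between scan days.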

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

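Of the tests of control replicate 2, the one on bright spots was chosen before its result was seen, and the other 3 after. Of the tests of the low p-values, the one on the correlation within arrays was chosen before. Those on the splits that keep arrays whole and on print blocks were chosen after. For the splits that part animals of an array, the order was not recorded. Single samples were set against the other 3 of their group in 16 sets of values, and 3 stood apart. Chance alone gives about 1 in 20.

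Control replicate 2 had a mean correlation of 0.789 with the other 7 samples, while the other controls had 0.920 to 0.928. A local defect of the slide is argued against, because its correlation with its array partner was under 0.9 in 48 of the 48 print blocks, against 0 blocks on each other array. Dim signal is argued against as the whole cause, because in the brightest 25% of spots the SD of the log ratio on its array was 3.17 times the mean of the other 3 arrays. Random noise alone is argued against, because its deviation from its array partner correlated with the difference between the second control array and the unloaded arrays, with a median r of 0.317 over 10 classes of intensity and 0.0802 in the lowest of them. A swap with one of the unloaded animals is argued against as the cause, because its highest correlation with any sample was 0.843, while the unloaded samples correlated at 0.904 to 0.971 with every sample except it. A different RNA, a fault in labelling its cDNA or an unusual animal stay open as untested, since the spots have no gene names, and no biological explanation was tested.

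The excess of low unadjusted p-values was the second pattern. Only 3 splits keep the animals of an array together, too few for a share under 0.05: the real split gave 2762 spots, as 1 of the 3, and the highest other 733. Of the 32 splits that part animals of an array, and so partly compare animals within arrays, 6 gave at least as many, up to 11899. The split with 11899 set control replicate 1 with the Cy3 samples of the other arrays and called 10015 spots after adjustment. With the dye term, it compares the log ratio of control replicates 1 and 2 with those of the other 3 arrays. Its count thus restates the discordance of that pair and is no evidence of a further structure. This split was not refitted without control replicate 2. When the correlation within arrays was taken from the 7 other samples, 453 spots of all 8 samples had a p under 0.05. That is fewer than the 1142 that 5% gives. A higher correlation widens the standard error of a difference between arrays, so the count would fall whatever had lowered the estimate. This count thus cannot decide whether a correlation lowered by the discordant pair of control replicates 1 and 2 made the excess. A limma fit on the mean of each array, an alternative chosen before the data were examined, uses no such correlation. It gave 2584 spots with a p under 0.05, of which 980 were higher and 1604 lower in unloaded brains. That argues against a lowered correlation as the whole cause. Without control replicate 1 the estimated correlation was 0.83 and 1825 spots had a p under 0.05, above 5%. A lowered correlation thus need not account for all of the excess. Print-block differences are argued against as the whole cause, because 2691 spots were left after centring on print blocks. An effect of array or scan day cannot be told apart from unloading, since each group has its own arrays and day, and the other 2 splits that keep arrays whole gave 733 and 543 spots.

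Unloaded replicate 2 had a mean correlation of 0.924 with the other samples, above the 0.903 to 0.906 of the other unloaded samples. At spot 21552, control replicate 4 had a log2 intensity of 11.90, below the 12.10 to 12.13 of the other controls.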

How the results depend on the processing

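Print-block centring and the combinations with control replicate 2 or its array left out were chosen after the data were seen. The count of 0 spots past the adjusted threshold was also found in 27 of 31 alternatives, and 0 spots passed in each of the 8 fits without 1 replicate. It was 1 with the foreground median, 2 without the second unloaded array, and 8 (4 higher, 4 lower) with the first control array left out and print blocks centred; the cause was not tested. At an unadjusted p under 0.05 and at least 1.5-fold there were 2165 spots, since that threshold takes no account of the number of tests. With the replicate block, 0 spots passed and 4214 had an unadjusted p under 0.05. The numbers do not pair the samples: same-numbered samples had deviations correlating from -0.47 to 0.30, and 1 of 8 samples correlated best with its own number. At an unadjusted p under 0.05 the counts ran from 674, in the authors' values, to 4838, and from 1300 to 4838 without each replicate in turn. The 4 spots given as examples were chosen without overlap of the groups, so leaving out samples could not turn them. The dye term, the array block and the kind of loess or median centring within arrays left their log2 differences unchanged, but not their adjusted p. These settings could not move the differences, since the dyes were balanced within groups and such centring shifts only ratios within arrays. Centring on print blocks made the log2 differences of all 4 spots smaller. Over all alternatives run, their adjusted p was 0.0934 to 0.891, and their log2 differences ran from -1.96 to -1.24 (spot 1918), -1.35 to -0.97 (spot 21552), 0.76 to 1.42 (spot 7688) and 0.63 to 1.403 (spot 2638). The spread within unloaded pairs, 0.173, was 0.167 for spots well above background in all 8 samples, 0.124 with print-tip loess and 0.129 with print blocks centred. Without each pair in turn it was 0.172 to 0.173, and that of the control pairs was 0.177 to 0.591. The comparisons of gene lists with their alternatives, and the mean of all spots of a gene, were not run, because no spot has a gene name. Signal over background limits the dim spots: 14653 were well above background in all 8 samples.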

Other observations

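The test below was chosen after the profile of control replicate 2 had been seen. A hypothesis is that the profile in which control replicate 2 departs from the other samples is also present, to a lesser degree, in the other brains, and that unloading may move samples along it. Each of the other 7 samples was scored by the slope of its own deviation on that profile, after print blocks were centred, so that control replicate 2 would score 1 if it were matched in full. The scores were 0.0327, 0.157 and 0.0559 for control replicates 1, 3 and 4, and 0.0479, -0.0293, -0.122 and -0.143 for unloaded replicates 1 to 4. The positive and negative scores cancel out in sum, so scores of both signs had to occur. Their signs alone therefore do not show that the other brains share the profile. The groups overlapped, with 3 of the 4 unloaded samples below all 3 other controls. The samples are too few to decide whether unloading moves samples along it, and each array holds 1 group, so array and unloading cannot be told apart here.

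Print blocks accounted for 16.3% of the variance of the group difference across spots, and for 24.3% without control replicate 2. The block medians of the difference between unloaded and control samples ran from -0.50 to 0.32 on the log2 scale. The position of a block and the sequences spotted in it were not separated.

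Of the 21549 spots that no array had flagged, 15 were well above background in all 4 unloaded and in 0 control samples, and 1 in all 4 control and 0 unloaded samples. In both directions together these were 16 spots, against 7 and 6 in the other 2 splits that keep arrays whole and at most 117 in the splits that part animals of an array. This measure rests on intensities before normalization. On the mean of its samples, each unloaded array had more spots well above background than each control array. The imbalance of 15 to 1 thus cannot be told apart from a difference in brightness between arrays.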
